A study of Mus musculus with 9 samples.

How the data were processed

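The series holds poly(A) RNA sequencing of mouse alveolar macrophages, the resident macrophages of the lung air spaces. Cells were recovered by bronchoalveolar lavage, a rinse of the airways. Each library comes from a pool of 5 to 7 mice of matched age and sex, 8 to 12 weeks old and on a C57BL/6 background, kept without treatment. Lavage cells were purified with magnetic beads against CD11c, the integrin alpha X chain that alveolar macrophages and dendritic cells carry, and RNA was used when its integrity value exceeded 8. Libraries were sequenced as single reads of 61 bases on an Illumina HiSeq instrument, per the labels' protocols. The strand setting of the library kit is not given in the sources used here. There are 3 genotypes with 3 pools each. Floxed controls carry a Vhl gene flanked by loxP sites on both alleles and no Cre recombinase. Cre controls carry Cre under the CD11c promoter with intact Vhl alleles. Vhl knockouts carry both the floxed alleles and the Cre transgene. Groups were taken from the genotype label, and all 9 libraries were used.

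Per the submitters' processing notes, CASAVA 1.8.2, cutadapt 1.3 and RSEM 1.2.3 were used with the GRCm38 genome build. CASAVA handles base calling and demultiplexing, cutadapt trims adapters, and RSEM estimates the number of reads per gene and divides reads that match several genes among them. The annotation, and the steps after RSEM, are not given in the sources used here. The authors deposited 1 table of 12003 Ensembl gene identifiers by 9 libraries, and its unit had to be found from the values. The deposited signal of each library is a whole number of reads multiplied by 1 library-specific factor, so the values are counts scaled to library size (CPM) after a normalization factor, called normalized reads, without correction for gene length. All values (100%) came out as whole reads within 0.01 read. The factors equalled trimmed mean of M values (TMM) factors recomputed from those reads, to within rounding. Such scaling assumes that most genes do not differ between libraries, so a shift shared by all genes cannot be seen. The table had been filtered before deposit, as each gene has a value of at least 0.962 in at least 3 libraries. Genes below that level are not analysed here, and this limits markers of rare cell types. No per-sample column was left out (0 columns).

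The recovered reads ranged from 18201116 (Cre control 3) to 25861174 (Vhl knockout 3) per library. In each library, 1 read equals 0.0400 to 0.0565 normalized reads. A count of 0 allows up to 3 reads, or 0.120 to 0.170 normalized reads. This limit covers counting error only, since reads without molecular identifiers are not independent molecules. Across the table, 112 genes were at 0 in at least 1 library. Libraries of the same group were compared in 9 pairs, and none were duplicates within counting noise. Symbols and positions came from GENCODE release M21 (GRCm38), which names 11935 of the identifiers and leaves 68 without a symbol.

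The test planned for counts, edgeR quasi-likelihood, was replaced by the test planned for normalized values, because the table holds scaled values. Values were transformed as log2(value + 1), which understates the change of low genes, and no gene was filtered out. A linear model with 1 mean per genotype was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. Tests were two-sided, p-values were adjusted over all 12003 genes with the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The contrasts were the knockout against the mean of both controls, against each control, and Cre controls against floxed controls. The last contrast is also the test of whether a knockout effect depends on the control used. P-values measure the spread between pools, and each pool averages several mice.

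Before the data were examined, 32 gene lists were fixed, covering metabolic, immune and growth programs, technical signs (mitochondrially encoded and dissociation stress genes) and markers of other cell types. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. P-values were adjusted over the 29 lists with at least 3 measured members. Older symbols were matched through synonyms. Members passing the test were counted after adjustment over all genes and, separately, adjusted over the list alone. A further 6 lists were written after the data had been seen and appear only among the closing observations.

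Genes named in the text follow a rule fixed before the data were examined. It takes Vhl, the 10 highest and 10 lowest fold changes among genes called against each control, with a mean of at least 5 normalized reads and no overlap between knockout and control libraries, and from each list up to 4 members with the smallest adjusted p and up to 2 well expressed members that did not pass. It also takes the 5 highest and 5 lowest changes between the controls, and genes that pass within 1 Mb of Vhl or Itgax. Any other gene is said to have been chosen after its values were seen. Means are given with their SD over libraries (n = 3 per genotype, n = 6 for both controls together).

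The scripts were tested on simulated reads for these 12003 genes with 200 changed genes. In the knockout against both controls, the test recovered 84% of genes changed 2-fold and 95% of those changed 4-fold, with 6 false calls. For the Cre controls against the floxed controls with no simulated change, there were 0 false calls. In simulated lists for the knockout against both controls over the same genes, camera and fry each recovered 5 of 5 changed lists with 0 false calls. The simulated genes varied independently, whereas the estimated correlation of the cell cycle list was 0.657. False calls in lists whose members vary together were therefore not tested. Alternatives covered other scalings, the pseudocount of 0.1, filters on mean value (1 and 5), a stricter adjusted p (0.01), a 2-fold minimum, fits with only the groups compared, the replicate number as a block, and leaving out each library. On the recovered reads, edgeR 4.0.16 quasi-likelihood, DESeq2 1.42.0 and limma-voom were run as alternatives. The edgeR test called 4739 genes in the knockout against both controls, 4676 of them shared with limma.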

Results

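Alveolar macrophages from 3 genotypes were compared by RNA sequencing, with 3 pools per genotype. The series title names terminal differentiation, self-renewal and function of these cells as the properties studied after loss of Vhl. VHL is the substrate-recognition part of the ubiquitin ligase that marks the alpha subunits of hypoxia-inducible factors (HIF) for degradation. Each library held 18201116 to 25861174 reads assigned to 12003 genes. Values are normalized reads (counts scaled to library size, CPM), given as mean ± SD (n = 3 pools per genotype, n = 6 for both controls together). Fold changes on the log2 scale come from limma on log2(value + 1). Per the labels the mice were matched for sex, and the sexes in each pool are not given. Xist, which is transcribed from the inactive X chromosome, ranged from 210 (Cre control 3) to 761 (floxed control 3) normalized reads. Of 4 Y-linked genes looked for, only 1, Kdm5d, was measured. It ranged from 2.72 to 5.24, also highest in floxed control 3, and alone does not show whether male cells were present. On the first principal component, with 61.7% of the variance, the knockout libraries lay at 41.3 to 45.7 and the control libraries at -25.3 to -19.2. On the second component, with 15.02% of the variance, library 1 of each genotype lay above libraries 2 and 3, at 33.9 against 2.33 and 2.97 in floxed controls, -0.600 against -19.3 and -18.02 in Cre controls, and 11.2 against -6.96 and -5.55 in knockouts.

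Vhl itself (ENSMUSG00000033933, chromosome 6, 113623959 to 113631633, GRCm38) was lower in the knockout, at 2.23 ± 0.261 normalized reads, than in floxed controls (18.1 ± 3.05) and Cre controls (23.7 ± 1.69). The knockout level was 10.6% of the control mean, and all 3 knockout libraries lay below all 6 controls. The log2 fold change was -2.75 (SE 0.110, limma adjusted p = 6.06e-08). The table sums reads over the whole gene, so it does not show which exons were lost. Between the controls, the Vhl mean was higher in Cre controls (log2 fold change 0.38, SE 0.128). Limma did not call this difference after adjustment over all genes (adjusted p = 0.573). That adjustment is strict for a single gene fixed in advance, so a lower Vhl level in floxed controls is not excluded.

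In knockout macrophages, most measured genes of glycolysis and other HIF targets rose, and most of cell cycle, cholesterol synthesis and interferon response fell. Camera called these lists at the preset correlation, but with an estimated correlation only the HIF targets were called (adjusted p = 0.0450), against an adjusted p of 0.189 for glycolysis, 0.567 for cell cycle and interferon response and 0.719 for cholesterol synthesis. Against both controls, 4781 genes (39.8%) were called by limma, 2361 higher and 2420 lower. Of these, 444 were higher and 325 lower by at least 2-fold. The steepest rise was in Egln3 (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), a prolyl hydroxylase that acts on HIF, from 2.06 ± 1.504 to 1698 ± 160 normalized reads (log2 fold change 9.23, SE 0.312, limma adjusted p = 1.66e-08). Arg1, the arginine-degrading arginase, rose from 0.906 ± 0.166 to 245 ± 12.99 (log2 fold change 7.02, limma adjusted p = 1.16e-11). Bnip3, a mitophagy receptor, rose from 16.2 ± 0.779 to 740 ± 89.7 normalized reads. The rest of the 10 top risers were Ndufa4l2, Ak4, Rtl5, Kcnj15, Vegfa, the coagulation factor gene F13a1 and the complement C3a receptor gene C3ar1, with log2 fold changes of 4.89 to 7.50. Among the 10 steepest falls, Igflr1 went from 42.0 ± 10.1 to 1.62 ± 0.372 normalized reads (log2 fold change -4.01, SE 0.182, limma adjusted p = 1.45e-07). Vhl, Cyfip2, Fscn1, Fads1, Ccr7, Syp, Adgre4, Siglece and Hspa1a had log2 fold changes of -2.94 to -2.68. Reads of Hspa1a cannot be cleanly told from its near-identical copy Hspa1b. Without a stated strand setting, the same holds where a named gene overlaps another measured gene, as for Rtl5, Ndufa4l2, Tpi1, Gys1, Ciita, Cyp51, Fdft1, Kif20a, Pltp, Ctsa, Cxcl16, Csf1r and Itgad.

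**Figure D1:**
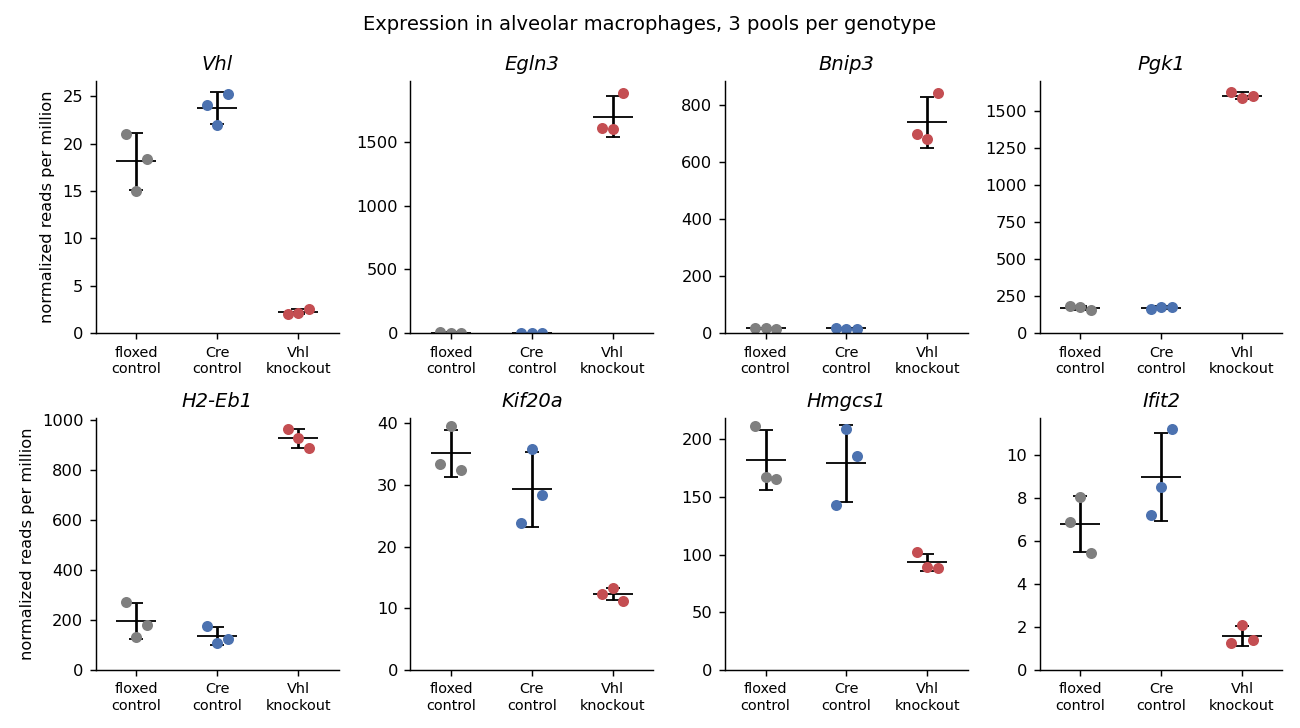
Normalized reads in CPM (vertical axis, from 0, own scale per gene) of 8 genes in floxed control, Cre control and Vhl knockout pools; points are libraries, horizontal lines are means and bars are SD (n = 3). In each panel the 3 knockout libraries lie outside the range of the 6 control libraries, above it for Egln3, Bnip3, Pgk1 and H2-Eb1 and below it for Vhl, Kif20a, Hmgcs1 and Ifit2.

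Of 34 measured HIF targets outside glycolysis, 30 rose, 1 fell and 3 did not pass (30 and 2 adjusted over the list alone). Besides Egln3 and Bnip3, Egln1 went from 52.2 ± 1.86 to 290 ± 12.7 normalized reads, and Gys1, which encodes muscle-type glycogen synthase, from 27.4 ± 2.52 to 221 ± 5.97. The member that fell was Hmox1, the heme-degrading heme oxygenase, from 729 ± 299 to 238 ± 39.0 (named after its values were seen). This list was called by camera (adjusted p = 9.93e-21) and also with an estimated correlation (adjusted p = 0.0450), which no other list was. In glycolysis, 19 of 22 measured genes rose and 1 fell (the same counts adjusted over the list alone). Pgk1 rose from 171 ± 10.5 to 1601 ± 21.6 normalized reads (log2 fold change 3.22, SE 0.0607, limma adjusted p = 3.96e-10). Tpi1 rose from 135 ± 7.76 to 1394 ± 37.6, Eno1 from 492 ± 35.4 to 2277 ± 58.2, and Gpi1 from 410 ± 18.9 to 1452 ± 30.3. Eno2, the neuronal enolase, fell from 1.18 ± 0.414 to 0.226 ± 0.168 (named after its values were seen). For glycolysis the camera adjusted p was 5.73e-15, and the adjusted p was 0.189 with an estimated correlation. Among VHL and HIF pathway components, 5 of 14 rose and 2 fell (5 and 2 adjusted over the list alone), and camera did not call this list (adjusted p = 0.167). The members that fell were Vhl and, named after its values were seen, Hif1a, from 151 ± 14.6 to 60.5 ± 2.57 normalized reads.

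Among cell cycle genes, 38 of 40 were lower and 0 higher (the same adjusted over the list alone), with a median log2 fold change of -0.82. The gene Kif20a, a kinesin of cell division, fell from 32.2 ± 5.55 to 12.3 ± 1.04 normalized reads (log2 fold change -1.31, SE 0.121, limma adjusted p = 2.14e-05). Mcm5, part of the replicative helicase, fell from 67.0 ± 12.1 to 32.1 ± 2.69, and Plk1, a mitotic kinase, from 16.0 ± 2.39 to 7.89 ± 0.198. For this list the camera adjusted p was 1.46e-14, and the adjusted p was 0.567 with an estimated correlation.

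In cholesterol synthesis, 21 of 24 genes were lower and 0 higher (23 lower adjusted over the list alone). Cyp51, a sterol demethylase, went from 114 ± 22.01 to 40.4 ± 7.93 normalized reads (log2 fold change -1.46, SE 0.166, limma adjusted p = 8.99e-05), Idi1 from 96.9 ± 19.5 to 40.0 ± 4.98, and Hmgcs1, which makes the precursor of mevalonate, from 180 ± 26.9 to 93.3 ± 7.48. Camera called the list with an adjusted p of 1.69e-08, and the adjusted p was 0.719 with an estimated correlation. In the interferon response list, 25 of 29 genes were lower and 0 higher (26 lower adjusted over the list alone). Ifit2 went from 7.90 ± 1.957 to 1.58 ± 0.452 normalized reads (log2 fold change -1.77, SE 0.166, limma adjusted p = 2.33e-05), and the antiviral gene Mx1 from 3.45 ± 0.491 to 0.619 ± 0.225. Camera gave an adjusted p of 9.35e-09 for interferon genes, and the adjusted p was 0.567 with an estimated correlation.

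Antigen presentation genes went both ways. In the MHC class II list, 9 of 14 genes rose and 3 fell (the same adjusted over the list alone). Ciita, the master regulator of class II transcription, rose from 16.8 ± 6.58 to 129 ± 6.08 normalized reads (log2 fold change 2.96, SE 0.238, limma adjusted p = 8.25e-06). The class II chain gene H2-Eb1 rose from 165 ± 59.9 to 928 ± 39.7. The 3 members that fell encode costimulatory molecules, which act beside class II rather than present antigen. They were Cd86, from 23.0 ± 2.85 to 8.29 ± 1.28, and, named after their values were seen, Cd40 and Cd80. The camera adjusted p was 0.0159, and the adjusted p was 0.851 with an estimated correlation. Of the dendritic cell markers, 12 of 15 were lower in the same libraries and 0 higher (13 lower adjusted over the list alone). Fscn1, which encodes an actin-bundling protein, went from 43.6 ± 21.4 to 4.43 ± 1.04 normalized reads and the chemokine receptor gene Ccr7 from 40.7 ± 20.98 to 4.31 ± 0.875. The camera adjusted p of these markers was 4.92e-06, and the adjusted p was 0.567 with an estimated correlation.

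**Figure D2:**
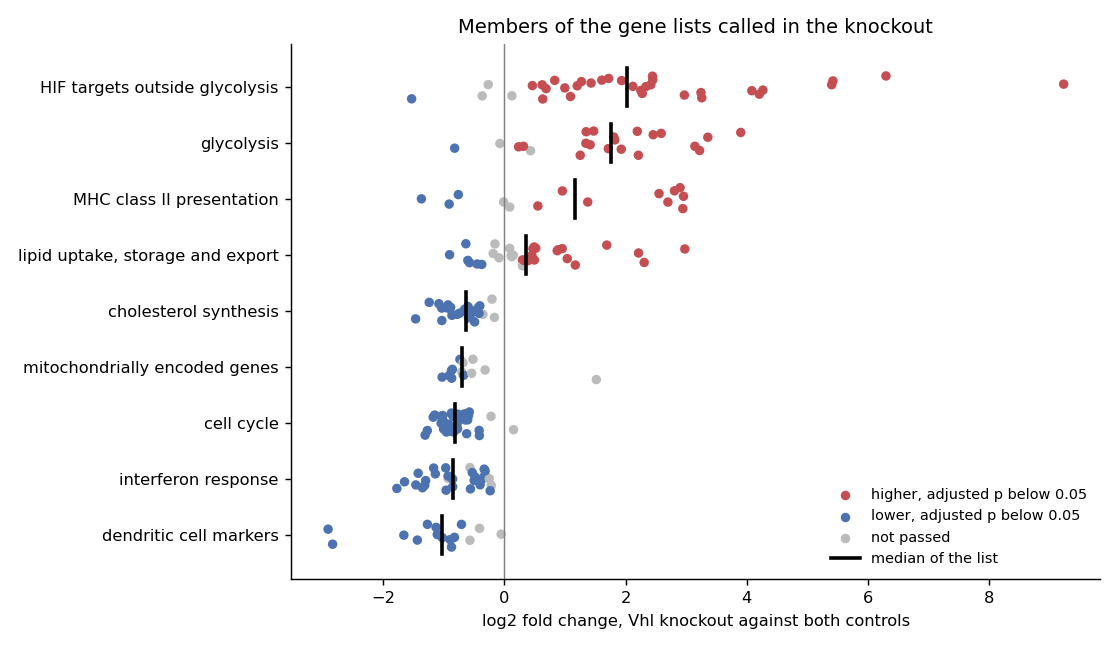
Log2 fold change of the knockout against both controls (horizontal axis) for each measured member of the 9 called lists; each point is a gene, coloured by limma adjusted p and direction, and the bar is the list's median. HIF targets, glycolysis, MHC class II and lipid handling lists have medians above 0, and the other 5 lists have medians below 0.

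Of 32 genes of lipid uptake, storage and export, 18 rose and 6 fell (the same adjusted over the list alone). Apoe, the apolipoprotein of cholesterol export, rose from 92.2 ± 25.1 to 715 ± 93.1 normalized reads (log2 fold change 2.98, SE 0.169, limma adjusted p = 6.71e-07). The phospholipid transfer protein gene Pltp rose from 163 ± 38.1 to 801 ± 111, and the desaturase gene Scd1 from 31.7 ± 4.18 to 105 ± 16.3. The camera adjusted p was 0.00339, and the adjusted p was 0.567 with an estimated correlation. Mitochondrially encoded genes were lower in 7 of 13 cases (9 adjusted over the list alone). They took 2.06 ± 0.316% of the reads in the knockout, 3.76 ± 1.59% in floxed controls and 3.58 ± 0.266% in Cre controls, with floxed control 1 highest at 5.59%. Camera called this list (adjusted p = 0.0156), the adjusted p was 0.851 with an estimated correlation, and without knockout library 2 the camera adjusted p was 0.0524.

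The mature alveolar macrophage list was not called (camera adjusted p = 0.258), with 10 of 29 markers higher and 5 lower. The cationic amino acid transporter gene Slc7a2 rose from 859 ± 41.9 to 2605 ± 319 normalized reads and the fatty acid binding protein gene Fabp4 from 89.5 ± 20.3 to 199 ± 20.3, while the keratin gene Krt79 fell from 400 ± 39.0 to 187 ± 21.5. Siglecf, a surface marker of these cells named after its values were seen, fell from 502 ± 58.7 to 334 ± 8.94. Well expressed markers that did not pass included Lpl, at 3248 ± 545 against 3683 ± 496. Growth and differentiation regulators were higher in 7 of 28 cases and lower in 5 (camera adjusted p = 0.886). Among them, the TGF-beta receptor gene Tgfbr1 fell from 608 ± 24.8 to 347 ± 4.40 and the growth factor receptor gene Csf1r from 450 ± 42.6 to 297 ± 16.4, and the transcriptional regulator gene Id2 rose from 116 ± 19.0 to 247 ± 25.6. Counts in both lists were the same adjusted over the list alone.

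Other metabolic lists were not called by camera against both controls with the deposited scaling and all libraries. Fatty acid oxidation had 8 of 26 genes higher and 4 lower (adjusted p = 0.433), with Ehhadh rising from 24.2 ± 2.12 to 37.8 ± 0.422. The tricarboxylic acid cycle had 2 of 22 higher and 5 lower (adjusted p = 0.388), with citrate synthase (Cs) falling from 253 ± 8.73 to 207 ± 4.28. Oxidative phosphorylation had 7 of 57 lower and 0 higher (adjusted p = 0.244), led by the cytochrome oxidase subunit gene Ndufa4, which fell from 76.8 ± 7.77 to 23.4 ± 1.54 normalized reads. Autophagy and mitophagy had 7 of 22 higher and 2 lower (adjusted p = 0.178), with Bnip3l rising from 334 ± 17.5 to 518 ± 21.1. Lysosome genes were lower in 14 of 35 cases and higher in 4 (adjusted p = 0.0868). Without floxed control 3, camera called oxidative phosphorylation (adjusted p = 0.00486) and lysosome (adjusted p = 0.0309) as lower, and lysosome also without Cre control 1 (adjusted p = 0.0377) and without a scaling factor (adjusted p = 0.0372). Psap, the saposin precursor, fell from 7118 ± 761 to 4415 ± 135, and Smpd1, acid sphingomyelinase, rose from 28.2 ± 2.65 to 72.7 ± 5.64. Adjusted over the list alone, the counts higher and lower were 8 and 5 for fatty acid oxidation, 0 and 4 for oxidative phosphorylation and 4 and 16 for lysosome, and as above for the tricarboxylic acid cycle and autophagy.

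Immune effector lists were mixed and not called by camera against both controls with the deposited scaling and all libraries. Inflammatory cytokines and chemokines had 7 of 22 lower and 1 higher (adjusted p = 0.127), with Tnf falling from 33.1 ± 6.43 to 8.87 ± 2.62 normalized reads. Without knockout library 1, camera called this list as lower (adjusted p = 0.0147). Alternative activation genes were higher in 3 of 12 cases and lower in 4 (adjusted p = 0.840). Of these, Arg1 and the receptor gene Il4ra rose, and the chemokine gene Ccl17 fell from 15.3 ± 6.94 to 2.09 ± 0.889. Phagocytic and scavenger receptors were higher in 7 of 24 cases and lower in 8 (adjusted p = 0.519). The inhibitory Fc receptor gene Fcgr2b rose from 209 ± 38.2 to 1022 ± 40.5, and the lectin receptor genes Clec4n and Clec7a fell, from 514 ± 70.9 to 135 ± 6.24 and from 1415 ± 178 to 552 ± 62.6. Extracellular matrix and angiogenesis factors were higher in 12 of 25 cases and lower in 5 (adjusted p = 0.0846), with the collagen hydroxylase gene P4ha1 rising from 64.5 ± 6.62 to 310 ± 11.7. Without floxed control 1, camera called it as higher (adjusted p = 0.0298), as it did without a scaling factor (adjusted p = 0.0249). Dissociation stress and immediate early genes were higher in 5 of 20 cases and lower in 3 (adjusted p = 0.488). Adjusted over the list alone, phagocytic receptors had 8 higher and 9 lower, and the counts of the other lists here were the same.

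Markers of other cell types, apart from those of dendritic cells, were not called by camera against both controls with all libraries. Monocyte markers were higher in 4 of 12 cases and lower in 3 (adjusted p = 0.394). F13a1 and Ace rose, Treml4 fell from 73.4 ± 20.8 to 17.97 ± 2.09, and the list's median log2 fold change was -0.01 while its mean and test pointed up. Interstitial macrophage markers were higher in 2 of 13 cases and lower in 7 (adjusted p = 0.151), and lung epithelial markers higher in 1 of 13 and lower in 5 (adjusted p = 0.136, and 0.0354 without floxed control 3). The epithelial surface gene Epcam fell from 71.5 ± 22.1 to 26.6 ± 2.08, and the E-cadherin gene Cdh1 rose from 117 ± 20.5 to 263 ± 11.9. B cell markers were higher in 1 of 4 cases (adjusted p = 0.488), neutrophil markers in 1 of 8 (adjusted p = 0.886), and T and NK cell markers lower in 1 of 8 (adjusted p = 0.519). These single members, Igkc, Mmp8 and Cd2, each lost their call with a library left out or another tool. Of the red cell markers, 0 of 4 passed (adjusted p = 0.388). Endothelial markers (1 lower of 2 measured), eosinophil, basophil and mast cell markers (1 lower of 1 measured) and fibroblast markers (0 measured) were too few to test. Adjusted over the list alone, B cell and neutrophil markers had 0 members passing, and counts of the other lists here did not differ.

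Against each control alone the knockout showed similar numbers. Limma called 4112 genes against floxed controls (2099 higher, 2013 lower), a contrast that holds the floxed alleles constant, and 4077 against Cre controls (1951 higher, 2126 lower), which holds Cre constant. Called in the same direction against each control were 3274 genes, 1642 higher and 1632 lower, and 3 were called in opposite directions. These were Plxnd1, Klrb1c and Eps8, all on chromosome 6 (Klrb1c was named after its values were seen). Both contrasts share the knockout libraries. With no effect simulated, the overlap was 0 genes in 20 simulations. These held no changed genes, so they cannot show how much of the observed overlap comes from the shared libraries. Independent lists of these sizes would share 341 higher and 357 lower genes. Part of the excess may come from the shared libraries. The covariance of the fold changes was 0.332, against 0.0134 simulated, and the correlation across genes was 0.890 against 0.498 simulated. The 9 lists above were called by camera against each control. Inflammatory (adjusted p = 0.0472) and interstitial macrophage lists (adjusted p = 0.0249) were also called against floxed controls. Extracellular matrix (0.0295), lysosome (0.0162) and oxidative phosphorylation (0.0295, camera adjusted p in each case) were also called against Cre controls. With an estimated correlation, the HIF list alone was called in either contrast, and whether the other lists differ between the contrasts was not tested beyond the comparison of the controls.

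The control genotypes were compared to show what differs without the knockout of Vhl. By limma few genes did, and most of those lie on chromosome 6. Limma called 20 genes, 8 higher and 12 lower in Cre controls (961 at an unadjusted p under 0.05). The lincRNA gene Gm26825 and the pseudogene Gm15459 overlap on chromosome 5 (5781530 to 5783636 and 5781615 to 5783555), so their reads cannot be told apart. Gm26825 stood at 313 ± 144 normalized reads in Cre controls and had 0 reads in all floxed libraries, at least 1922-fold higher against a floor of 3 reads in a library, but edgeR did not call it (adjusted p = 0.0946). On chromosome 6, Eps8, which encodes an actin-regulating signalling protein, was at 63.3 ± 5.00 in Cre controls and 13.04 ± 1.29 in floxed controls (log2 fold change 2.20, SE 0.101, limma adjusted p = 7.13e-06). Clec1b, which encodes a lectin receptor and overlaps Clec9a on the same strand, was at 17.9 ± 2.72 and 1.06 ± 0.163. Lower in Cre controls were Emp1 (81.9 ± 14.5 against 211 ± 18.8), Ptpro (19.0 ± 1.99 against 35.8 ± 2.25) and Mgst1 (213 ± 12.1 against 345 ± 27.8). The count depends on the method, with 16 genes by edgeR, 74 by DESeq2 and 13 by limma-voom. It was 11 with only these groups in the fit, 71 with a replicate block, 31 without Cre control 1 and 13 without Cre control 3. The share on chromosome 6 was worked out for the 20 genes only.

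**Figure D3:**
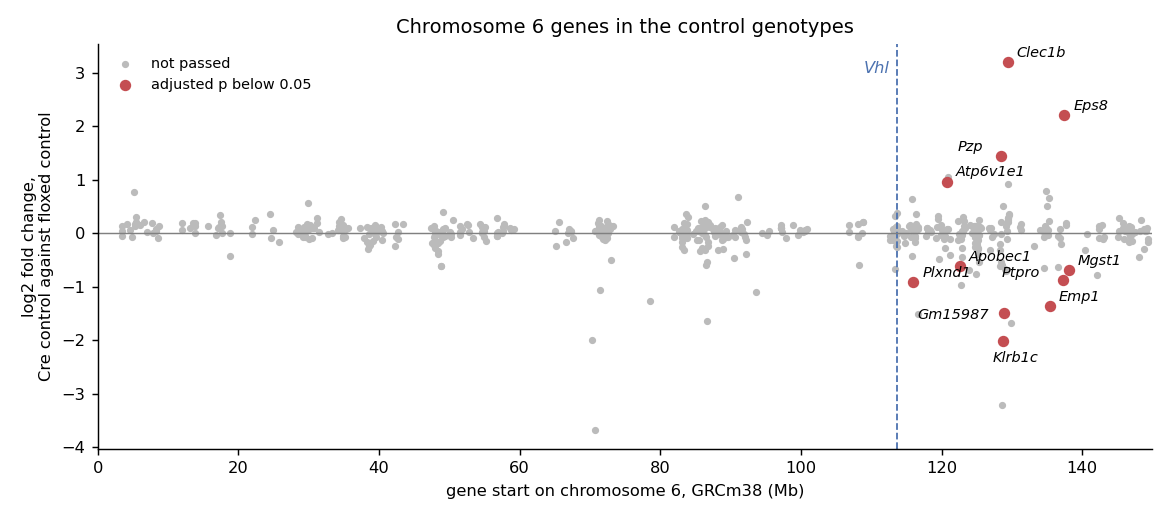
Log2 fold change of Cre controls against floxed controls (vertical axis) by gene start on chromosome 6 in Mb (horizontal axis, GRCm38); red points are genes with a limma adjusted p under 0.05, and the dashed line marks Vhl. The 11 called genes start between 116 and 138 Mb, on the distal side of Vhl.

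Gene lists differed little between the controls at the level of single genes. Camera at the preset correlation called 15 lists, 8 lower and 7 higher in Cre controls, and with an estimated correlation it called 0. The cell cycle list was lower in Cre controls (median log2 fold change -0.24, camera adjusted p = 4.55e-12, adjusted p = 0.457 with an estimated correlation), with 0 of 40 members passing over all genes or adjusted over the list alone. B cell markers were lower in Cre controls (camera adjusted p = 1.01e-05, adjusted p = 0.403 with an estimated correlation), with 0 of 4 members passing over all genes and 4 adjusted over the list alone. Markers of other cell types were also lower in Cre controls by camera, but not with an estimated correlation. They were those of monocytes (median log2 fold change -0.63, camera adjusted p = 2.25e-05, adjusted p = 0.403 with an estimated correlation, 5 of 12 lower adjusted over the list alone), interstitial macrophages (-0.61, camera adjusted p = 9.75e-06, then 0.403), neutrophils (-0.98, camera adjusted p = 0.00203, then 0.508) and T and NK cells (-0.54, camera adjusted p = 0.00253, then 0.457). The dissociation stress list (median log2 fold change -0.26, camera adjusted p = 2.82e-04, then 0.403) and cholesterol synthesis (-0.11, camera adjusted p = 0.00597, then 0.696) were lower as well. The 7 lists higher in Cre controls had medians of 0.06 to 0.15. They were fatty acid oxidation (camera adjusted p = 1.88e-05, then 0.457), oxidative phosphorylation (2.25e-05, then 0.675), lysosome (8.90e-05, then 0.508), mature alveolar macrophage markers (2.82e-04, then 0.457), lipid handling (5.77e-04, then 0.403), the tricarboxylic acid cycle (0.00710, then 0.535) and phagocytic receptors (0.0495, then 0.457), each as camera adjusted p and that with an estimated correlation. Among the members of these 15 lists, only Klrb1c and Fcgr2b, both lower, passed over all genes. Igkc was at 26.6 ± 32.9 in floxed controls, 0.257 ± 0.181 in Cre controls and 14.9 ± 4.83 in the knockout.

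Genes near Vhl were examined because targeted alleles can carry or disturb their neighbours. Those near Itgax were examined because Cre is under the CD11c promoter. The genotype labels do not give the site of the Cre transgene, so this second window does not test its insertion. Within 1 Mb of Vhl, 9 of 23 other measured genes were called in the knockout against both controls (39.1%, against 39.8% of all genes), 5 higher and 4 lower. Among them, Fancd2, a DNA repair gene, went from 12.5 ± 2.23 to 7.08 ± 0.935 normalized reads and Srgap3 from 7.62 ± 0.701 to 20.4 ± 5.52. Within 1 Mb of Itgax, the CD11c gene, 15 of 50 were called (30%). The integrin gene Itgad, next to Itgax, rose from 29.0 ± 14.9 to 196 ± 12.5 (log2 fold change 2.84, SE 0.229, limma adjusted p = 8.32e-06). Itgax was at 1897 ± 75.7 in the knockout, 1715 ± 38.9 in floxed controls and 2505 ± 353 in Cre controls. In neither window did limma call any gene between the controls.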

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

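The tests of position on chromosome 6 and of which control the knockout resembles were chosen after the result was seen. So were the use of edgeR on the recovered reads and the fit without a scaling factor. The contrast between the control genotypes tests whether a knockout effect depends on the control used, and 20 genes passed it. In 10 splits of the 6 control libraries, the real split gave 20 genes and the highest other split 1, and 10 splits are too few for a share under 0.05. Of the 20 genes, 11 lie on chromosome 6 (55%, against 4.79% of measured genes with a position), all 11 distal of Vhl, where 205 measured genes lie. Chance placement over the genome is argued against by a two-sided Fisher's exact test (p = 3.16e-10), although neighbouring genes are not independent. An effect of the Cre transgene would put the knockout, which carries Cre, near the Cre controls. The knockout was nearer to these for 3 of the 11 genes. They were Eps8 and, named after their values were seen, Pzp and Apobec1. For Eps8 the knockout (30.4 ± 3.42 normalized reads) lay between the controls and was called against each. A linked chromosomal segment carried with the floxed allele would put the knockout near the floxed controls, and the knockout was nearer to these for 8. Outside chromosome 6, it was also nearer to floxed controls for each gene called between the controls except Plcb4 and Siglech. Nearness alone therefore does not show linkage. Within 1 Mb of Vhl, limma called 0 of 23 other genes between the controls. Nearer does not mean equal. Of the 11 genes, the knockout was called against Cre controls only for 4, against floxed controls only for 1 and against both for 6. Such a segment may underlie part of these differences. The distance test does not remove the effect of Vhl loss itself, which also moves some of these genes, as for Emp1 (484 ± 36.5 in the knockout, above both controls). It therefore cannot exclude a Cre effect for such genes, and no strain genotype was tested.

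Outside chromosome 6, 9 genes differed between the controls, counting the overlapping Gm26825 and Gm15459 separately. Gm26825 and Gm15459 were at 313 ± 144 and 338 ± 172 normalized reads in Cre controls, and at 0.170 ± 0.295 and 0.329 ± 0.304 in the knockout. The phospholipase gene Plcb4 was at 22.4 ± 6.44 in Cre controls, 2.13 ± 1.86 in floxed controls and 12.2 ± 1.69 in the knockout. Gm6166, a pseudogene whose reads can be shared with its parent gene, was at 0.0523 ± 0.0906 in Cre controls and 24.7 ± 16.6 in floxed controls. In the knockout Gm6166 was at 19.1 ± 12.5. Fcgr2b was at 176 ± 15.8 in Cre controls and 243 ± 7.29 in floxed controls, both far below the knockout. The other 4, named after their values were seen, were the insulin-degrading enzyme gene Ide, higher in Cre controls, and Cd209c, Siglech and Gm11380, lower in Cre controls. Over 15 alternative fits that kept all genes, 8 of the 20 calls held in each, all 8 on chromosome 6, and 12 were lost in at least 1. With only the control groups fitted 11 of the 20 were called, by limma-voom 13 and without Cre control 3 also 13. Fcgr2b was lost in 9 of these fits, Siglech in 8 and Gm11380 in 6, with a highest adjusted p of 0.196, 0.268 and 0.225. For the others outside chromosome 6, the highest adjusted p was 0.657 for Gm6166, 0.184 for Cd209c, 0.148 for Gm26825, 0.141 for Plcb4, 0.0651 for Ide and 0.0599 for Gm15459. On chromosome 6, the calls of Plxnd1 (0.0549), Pzp (0.0512) and, named after its values were seen, Gm15987 (0.0651, highest adjusted p in each case) were lost with only the control groups fitted, and Gm15987 also without Cre control 3.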

How the results depend on the processing

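The use of edgeR on the recovered reads and the values without a scaling factor were chosen after the data were seen. So were the fits without chromosome 6 genes, the wider NRF2 list and the splits of 3 libraries against 6. No called list or called named gene reversed its direction under any alternative run. Vhl kept its call throughout, with log2 fold changes of -2.81 to -2.69 when single libraries were left out. Over 201 named genes, 4027 results kept their side of the threshold, 49 became significant and 69 lost significance. The naming rule favours large changes and small adjusted p, so these counts do not stand for all called genes. At an adjusted p under 0.01, the knockout counts were 3131 (both controls), 2545 (floxed), 2437 (Cre) and 1998 (same direction). With a 2-fold minimum they were 769, 819, 776 and 622, and 13 between the controls. These follow from stricter thresholds. Leaving out each library gave 3648 to 4974 genes against both controls, 3098 to 3880 against floxed controls, 3052 to 3808 against Cre controls, 2462 to 2654 in the same direction (knockout libraries only), 13 (without Cre control 3) to 31 (without Cre control 1) between the controls, and 8 to 12 called lists. Between the controls, the count was 6 without chromosome 6 genes, 11 with only these groups fitted, 13 by limma-voom, 74 by DESeq2, 16 by edgeR and 71 with a replicate block. Removing chromosome 6 removes the 11 genes called there, and the cause of the other shifts was not tested. Of the 9 lists called by camera in the knockout against both controls, 1 was called with an estimated correlation, fry called 14 lists, and camera without a scaling factor 11. By fry, alternative activation, autophagy, extracellular matrix, mature alveolar macrophage, monocyte and VHL and HIF component lists were also called, and the mitochondrially encoded list was not (adjusted p = 0.0920). The labels do not say what a replicate number marks, and same-numbered libraries did not all deviate together. Correlations ran from -0.09 to 0.52, over 0.1 in 6 of 9 pairs, and 3 of 9 libraries correlated best with their own number. The 3 pairs of libraries numbered 1 were at 0.20, 0.32 and 0.52, so a factor shared by these libraries stays open. The block called 4898 genes against both controls, 4592 of them shared. The planned comparison of no filter on low values equals the reported analysis. The balance of directions against both controls depended on the scaling, with 1925 genes higher and 2838 lower without a scaling factor, 2227 and 2606 with upper quartile scaling, and 2366 and 2402 with relative log expression. Depth limits statements on genes under about 1 normalized read, and on markers missing from the table.

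Other splits of the libraries were tested for the counts of changed genes. Among the 84 splits of 3 libraries against the other 6, fitted with 2 means, the real split gave 4728 genes and the highest other split 7. Only 1 of the 84 splits, the real one, gave as many genes, a share under 0.05 that argues against chance. Every other split puts knockout and control libraries on the same side, which widens the spread, so the size of the gap adds little. For the knockout against floxed and against Cre controls, 10 splits are too few for a share under 0.05. The real counts were 4112 and 4077, and the highest other count was 0 in each.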

Other observations

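The 6 gene lists described here were written, and the genes named from them and the class II genes below picked, after the data had been seen, as were the wider NRF2 list and the tests of more dendritic cells, of fewer dendritic cells and of more B cells below. Of 18 NRF2 targets, the genes of the oxidative stress regulator NRF2, 16 were lower and 1 higher (camera adjusted p = 8.87e-06, adjusted p = 0.379 with an estimated correlation). The thioredoxin reductase gene Txnrd1 fell from 293 ± 59.4 to 103 ± 4.64 normalized reads, Srxn1 from 110 ± 32.3 to 39.8 ± 4.69, and Gclm, which encodes a subunit of the enzyme that starts glutathione synthesis, from 104 ± 30.2 to 42.1 ± 2.505. Iron handling genes were lower in 8 of 13 cases and higher in 1 (camera adjusted p = 0.00753, adjusted p = 0.379 with an estimated correlation). The iron exporter gene Slc40a1 fell from 26.9 ± 7.23 to 7.00 ± 1.34 and the transferrin receptor gene Tfrc from 24.9 ± 3.98 to 12.7 ± 0.643.

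Cytosolic ribosomal protein genes rose by small amounts in 16 of 33 cases, with 0 lower and a median log2 fold change of 0.23 (camera adjusted p = 5.90e-04, adjusted p = 0.514 with an estimated correlation). Complement genes split, with 6 of 17 higher and 6 lower (camera adjusted p = 0.887). C4b rose from 4.56 ± 0.646 to 74.6 ± 21.1 normalized reads and C3ar1 from 4.99 ± 2.02 to 169 ± 17.4, while C3 fell from 615 ± 177 to 117 ± 21.1 and Cfb from 466 ± 182 to 106 ± 17.7. Arachidonic acid enzymes and receptors were lower in 7 of 16 cases and higher in 2 (camera adjusted p = 0.0647). The cyclooxygenase gene Ptgs1 fell from 13.02 ± 2.89 to 3.57 ± 0.260.

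Higher MHC class II genes came with lower dendritic cell markers, although dendritic cells carry CD11c and pass the bead selection. More dendritic cells in the knockout pools are argued against by the median log2 fold change of their 15 markers, -1.02. More B cells are argued against by their markers Ighm, Igkc, Jchain and Fcrla, which added up to at most 0.354% of the rise of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 in any knockout library (19.2 to 33.4 against 8838 to 9741 normalized reads). A smaller share of dendritic cells is neither shown nor excluded, since the 15 markers stood at 11.3 to 96.4% of the controls on the log2(value + 0.1) scale, not at one shared ratio, and the highest, at 2.57 times the median, was Cd24a, whose high baseline would hide a loss (140 ± 1.97 against 148 ± 34.1). A smaller share would not raise class II genes, and a rise within the macrophages may be a second change, which was not tested. Only dendritic and B cells were weighed, so other cell types are not excluded as a source of the rise. Monocyte markers had 4 of 12 higher and 3 lower. Interstitial macrophage markers had 2 of 13 higher, among them Itgam, and 7 lower. None of the 15 dendritic cell markers is on another list (0).

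Slc7a11, which imports cystine, fell from 166 ± 68.2 to 24.1 ± 4.68 normalized reads (log2 fold change -2.66, SE 0.288, limma adjusted p = 6.56e-05), and Nqo1 and Hmox1 had log2 fold changes of -2.12 and -1.53 (all 3 chosen after their values were seen). A fall shared by other NRF2 targets stays a hypothesis, since the NRF2 list, written after these 3 genes were seen and without them, was lower (camera adjusted p = 8.87e-06) but was not called with an estimated correlation (adjusted p = 0.379). The target gene Mgst1, whose rise from 279 ± 74.7 to 460 ± 17.7 had been seen, is not on that list. Mgst1 also differed between the controls, and its log2 fold change was 0.415 against floxed and 1.10 against Cre controls. With Mgst1, Fth1 and Ftl1 added, 17 of 21 were lower and 2 higher (camera adjusted p = 7.29e-05, adjusted p = 0.399 with an estimated correlation). A fall shared by other ATF4 targets, the genes of the amino acid stress regulator ATF4, stays open, since their list without these genes was not called (camera adjusted p = 0.265), but with 4 members higher and 8 lower of 19 a missed threshold, which had been set in advance as evidence against it, decides nothing.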
